A study of Mus musculus with 20 samples.

How the data were processed

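RNA from 3 bone marrow populations, double sorted after enrichment for c-kit (GMP, early promyelocytes and late promyelocytes), of wild-type and MRP8-PML/RARa transgenic FVB/n mice aged 3 weeks 5 days was hybridized to 20 one-colour Agilent mouse arrays after 2 rounds of amplification, per the labels. Each sample is a mix of male and female mice in equal parts. Per the file headers, each of the 20 spot files holds linear intensity values from Agilent Feature Extraction 10.7.3.1: the processed signal after the software's background subtraction and detrending within the array, and the median pixel signal of each spot and of its local background. The deposited value table holds log2 values that the authors made by quantile normalization; the submitters name limma for it and give no version. Its order of spots within each array followed the median signal (Spearman correlation of 1 on each array), and its median per array lay between 6.18 and 6.22.

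Of 42703 spots per array, 1417 were controls, and the others held 41188 probes. The files give accessions and no gene symbols, so each probe's RefSeq accession was looked up in a table of names from assembly GRCm38.p6, which was used for names only, since the array headers name mm9 and no genome positions are printed here. A symbol was found for 24844 probes (17178 symbols), and 16344 probes without a single symbol were tested separately. Members of the gene lists were matched by current symbol or, where absent, by an alias listed beside it. Kit and Cebpe, which had been chosen to be named, had no symbol by this route and are not analysed here, and 2 members of the lists are not reported here by name. Spots with the software's outlier flags (370) were left out, which left 355 probe values missing, so that a few bright genes such as S100a8, S100a9, Mpo and Elane have fewer values than arrays. No spot was saturated (0).

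The processed signal was put on the log2 scale and shifted so that the 75th percentile of each array was 0. A probe was kept when it was well above background on at least 3 arrays of at least 1 of the 6 groups (29015 probes, 19905 with a symbol), and each gene was represented by its brightest probe, which gave 13912 genes. Between 51.5 and 85.6% of the probes of an array were well above background. Differences were tested with limma 3.58.1 in R 4.3.3 (files read with the data.table package, version 1.17.8), fitting a mean per group over all 20 samples and moderated variances, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. The comparisons were PML/RARa against wild type in each population and averaged over the 3, the differences of these effects between populations, and each population against the next within a genotype. Replicate numbers were not used to pair samples. Residuals of samples on the same slide had a mean correlation of 0.218 over 30 pairs, so values with slide as a block are given. Slides 1 to 5 carry 4 arrays each, and all were scanned on 1 day.

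Gene groups were 29 lists (632 genes) written from general knowledge of the field, of which 27 were tested with camera in limma at its preset correlation of 0.01, adjusted over the 81 tests of the genotype comparisons together, and again with a correlation estimated from the data and with fry. The transgene-related and sex-linked lists are given by gene. Where a list is said to be adjusted over the list alone, the p-values of its members were adjusted among themselves. The genes named were set by rule: in each comparison the genes with the largest change past the threshold whose samples did not overlap and whose probe was well above background on every array of the brighter group, the members of each list with the smallest p, Pml, Rara, S100a8 and S100a9 throughout, a set of granule and proliferation genes for the populations, and members of counts of 5 or fewer. A fold change is written as at least a value when the gene was above background on 0 arrays of the dimmer group, and it is then measured against the background level of that group. Correlations with wild-type maturation use a maturation step that shares no array with the genotype effect, and their p is an exact permutation of the genotype labels.

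The grouping, tests, rule for naming genes, lists and most alternatives were set before the data were examined. The alternatives were quantile normalization, normexp background correction with an offset of 50 (with the median signal, since the files hold no mean signal) followed by either scaling, the value table of the authors, other filters on dim probes (none, or 10 arrays), the mean over a gene's probes, other estimates of the spread, array weights, the compared groups alone, replicate or slide as a block, PML/RARa late replicate 1 counted as early, each array left out in turn, and an adjusted p under 0.1. Leaving out the dim and the bright arrays, keeping outlier spots and testing accessions without a symbol were added after seeing the data. A block for the scan day could not be fitted, as all arrays share it. Tested on simulated data with the same group sizes, 100 genes changed by 1 on the log2 scale were recovered as 12 in GMP, 8 in early and 6 in late promyelocytes, and those changed by 2 as 70, 69 and 62, with 5, 5 and 0 false calls. The simulated noise was independent between genes and arrays, with no slide effect and no dim or bright array. Its false calls may therefore be fewer than those of the real arrays. A gene that did not pass leaves changes of 1 open, and some changes of 2.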

Results

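Gene expression was profiled in 3 sorted myeloid populations of mouse bone marrow, GMP (the label used for granulocyte-macrophage progenitors), early promyelocytes and late promyelocytes. The cells came from wild-type FVB/n mice and from mice that carry an MRP8-PML/RARa transgene, which encodes the fusion protein of acute promyelocytic leukemia under a promoter active in myeloid cells. Wild type gave 3 samples of each population, and PML/RARa gave 4 samples of GMP, 3 of early promyelocytes and 4 of late promyelocytes. Signals are given on the log2 scale relative to the 75th percentile of each array, as mean ± SD, and differences as log2 fold change ± SE with the adjusted p of limma over 13912 genes. The samples are biological replicates by the series design. The p-values rest on a spread between replicates that is estimated over all 20 samples and moderated across genes, not on the compared samples alone. Slide does not enter it unless stated.

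The arrays differed in brightness most among the GMP. The 75th percentile of the signal was 36.2 for wild-type GMP replicate 3 and 1673 and 1804 for PML/RARa GMP replicates 3 and 4, against 104 to 251 for the other 17 arrays. Wild-type GMP replicate 3 also had the lowest mean correlation with the other arrays, 0.808. The GMP counts, and the medians of the lists that passed in GMP, are therefore also given without the dim array and without all 3. The labels of PML/RARa late replicate 1 differ, late promyelocyte in its title and early promyelocyte in its stage field. It was grouped as late: across the 612 genes tested for this its profile correlated at 0.906 with the difference between late and early promyelocytes.

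**Figure D1:**
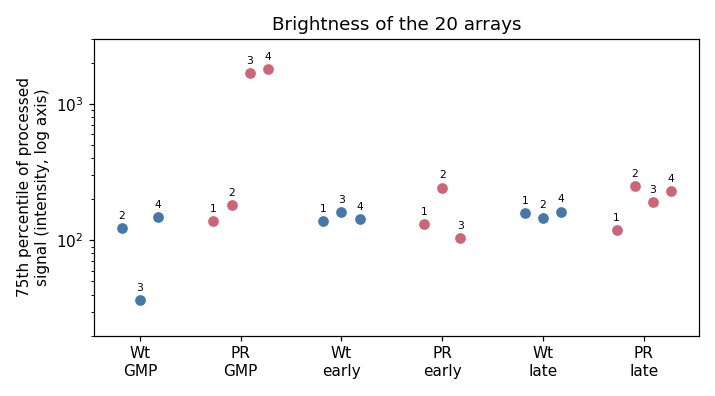
Brightness of the 20 arrays, as the 75th percentile of the processed signal (log axis), by genotype (Wt, wild type, PR, PML/RARa) and population, with replicate numbers. Wild-type GMP replicate 3 lies at 36.2 and PML/RARa GMP replicates 3 and 4 at 1673 and 1804.

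The comparison of the populations within wild type shows the course of granulocyte maturation. From GMP to early promyelocytes, genes of neutrophil granules and of the S100 calcium-binding proteins rose most. Lactoferrin (Ltf) was above background on 3 of 3 early promyelocyte arrays and 0 of 3 GMP arrays. It was at least 551-fold higher (adjusted p = 1.72e-06). The cathelicidin gene Camp was at least 116-fold higher and Retnlg, which encodes a resistin-like secreted protein of granulocytes, at least 144-fold higher. S100a9 rose by 8.74 ± 0.71 (adjusted p = 2.88e-06) and S100a8 by 8.10 ± 0.71 (adjusted p = 5.88e-06). Gzmb, a granzyme gene, fell to background on all 3 early promyelocyte arrays and was at least 21.5-fold lower, and the water channel gene Aqp1 (-7.17 ± 0.90), the thrombin receptor gene F2r (-4.96 ± 0.50) and the carbonic anhydrase gene Car1 (-4.71 ± 0.63) fell as well. In all, 779 genes passed, 423 higher and 356 lower, against 2501 and 675 with normexp and the 75th percentile. Without the dim GMP array 680 passed, 529 of the 779 among them. Without it and the bright GMP arrays 732 passed, 548 of the 779 among them.

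Secondary and tertiary granule genes were the group with the largest rise: 15 of 21 rose, 0 fell and 6 did not pass, with a list median of 2.94 (camera adjusted p = 3.21e-26, adjusted p = 0.0041 with an estimated correlation). Monocyte and macrophage genes rose too (median 1.73, 15 of 24 higher and 1 lower, adjusted p = 2.82e-11, 0.00643 with an estimated correlation). Primary granule genes had a median of 0.95 with 7 of 15 higher (adjusted p = 1.96e-06, 0.0662 with an estimated correlation). The primary granule protease gene Elane rose by 2.25 ± 0.56 (adjusted p = 0.0312), while Mpo (-0.56 ± 0.55, adjusted p = 0.611) and Ctsg (0.95 ± 0.36, adjusted p = 0.166) were already bright in GMP, at 8.45 and 6.83. Stem and progenitor genes fell (median -1.31, 13 of 25 lower and 2 higher, adjusted p = 3.75e-11, 0.00588 with an estimated correlation), as did erythroid (-1.66, 9 of 21), megakaryocyte (-1.21, 6 of 14) and mast cell and basophil genes (-1.57, 5 of 15). These 3 lists passed with an estimated correlation as well, at adjusted p = 0.00588, 0.00588 and 0.026.

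From early to late promyelocytes in wild type, 674 genes passed, 267 higher and 407 lower (196 and 185 with normexp and the 75th percentile). The adhesion receptor gene Vcam1 rose by 4.76 ± 0.32 (adjusted p = 2.66e-07), the acyltransferase gene Mogat2 by 5.33 ± 0.56 and the septin gene Septin5 by 4.50 ± 0.56, and the thyrotropin receptor gene Tshr was at least 16.2-fold higher. Cpa3, a mast cell carboxypeptidase gene, was at least 49.3-fold lower. Gata2 (-6.82 ± 0.62, adjusted p = 4.24e-06), Cd34 (-4.75 ± 0.49) and the homeobox gene Meis1 (-4.29 ± 0.67) fell as well. Rara itself, the gene of retinoic acid receptor alpha, fell by 2.06 ± 0.26 (adjusted p = 9.23e-05). Secondary and tertiary granule genes rose further (median 1.67, 11 of 21 higher, camera adjusted p = 2.27e-13, 0.0132 with an estimated correlation), and stem and progenitor genes fell further (median -1.20, 9 of 25 lower, adjusted p = 1.12e-11, 0.00588). All 28 ribosome biogenesis and MYC target genes were negative, with a median of -0.42, though none passed alone (adjusted p = 0.000356, 0.192 with an estimated correlation).

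PML/RARa cells passed through much of the same course. Early promyelocytes differed from GMP in 823 genes (330 higher, 493 lower). Late promyelocytes differed from early ones in 803 (395 higher, 408 lower, with a median over all genes of 0.12). With normexp and the 75th percentile these were 233 higher and 249 lower, and 248 and 231. With quantile normalization they were 205 and 434, and 356 and 414. Of the first step, 211 higher and 255 lower genes passed in both genotypes, against 10.03 and 12.6 by chance. None (0) passed in opposite directions, and r across all genes was 0.561. Of the second step, 202 higher and 266 lower genes were shared, against 7.58 and 11.9 by chance. A single gene (1) passed in opposite directions, and r was 0.594. S100a9 rose by 7.01 ± 0.66 from GMP to early promyelocytes, Chil3, a chitinase-like gene of myeloid cells, by 7.19 ± 0.85 and Camp by 5.17 ± 0.71. Cpa3 fell by 7.53 ± 0.50, and the IgE receptor chain gene Ms4a2 was at least 34.0-fold and the transporter gene Slc22a3 at least 33.0-fold lower. In the second step Camp rose by 5.54 ± 0.71 (adjusted p = 7.69e-05), while Ly86, a partner of a B cell and macrophage receptor, fell by 5.46 ± 0.35 (adjusted p = 5.42e-08), and Ms4a6b fell by 5.25 ± 0.59. Rara, which fell in wild type, was 0.60 ± 0.24 higher in late than in early PML/RARa promyelocytes (adjusted p = 0.199). Mki67, a proliferation marker, differed by no more than 0.61 ± 0.27 at any step in either genotype, with adjusted p from 0.262 to 0.988. From GMP to early promyelocytes in wild type it reached 1.36 with normexp and the 75th percentile, where alone of 38 alternatives it passed (adjusted p from 0.0171 to 0.803 over these).

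In GMP, 18 of the 19 genes that passed were higher in PML/RARa than in wild type. Lcn2, which encodes an iron-siderophore-binding protein of neutrophil granules, was well above background on 4 of 4 PML/RARa arrays and 0 of 3 wild-type arrays and was at least 4.9-fold higher (adjusted p = 0.0354). The antiproteinase-like gene Wfdc21 rose by 3.16 ± 0.53 (adjusted p = 0.0233), from -2.46 ± 0.59 (n = 3) to 0.70 ± 0.79 (n = 4). The myeloid receptor gene Trem3 rose by 2.42 ± 0.24 (adjusted p = 0.000147), from -1.99 ± 0.40 to 0.43 ± 0.31. Haptoglobin (Hp, 2.08 ± 0.34), the oxidase subunit gene Cybb (1.56 ± 0.26), the chitinase-like gene Chil1 (2.46 ± 0.40), the sphingomyelin synthase gene Sgms2 (2.88 ± 0.42), the lectin receptor gene Clec5a (2.60 ± 0.48) and the monocyte surface gene Ly6c1 (2.05 ± 0.38) rose too. In wild-type GMP, Trem3, Chil1, Sgms2 and Clec5a were above background on 2 of 3 arrays. A single gene, the stem and progenitor cell adhesion receptor gene Adgrg1, fell by 2.05 ± 0.34 (adjusted p = 0.0233). Next after it, short of the threshold, were the platelet gene Plek (-1.45 ± 0.28, adjusted p = 0.0511) and Tmem132a (-1.62 ± 0.32, adjusted p = 0.0536).

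The median over all genes was -0.12 in GMP, and in all 19 genes the genotypes did not overlap. Trem3 differed by 1.70, 2.62 and 2.53 on slides 1, 2 and 3 and Adgrg1 by -1.08, -2.90 and -1.54. With slide as a block 24 genes passed, 17 of the 19 among them, and Clec5a did not (adjusted p = 0.0735). Of the 19 genes, 7 had another probe that passed the filter, and in 3 of these, Clec5a among them, another probe had the opposite sign. The other probes of Clec5a gave -0.39 and 2.26. Rara differed by 0.55 ± 0.24 (adjusted p = 0.267), Pml by -0.62 ± 0.25 (adjusted p = 0.246), S100a8 by 2.34 ± 0.66 (adjusted p = 0.171) and S100a9 by 1.10 ± 0.66 (adjusted p = 0.391). The GMP counts moved when arrays were left out: without the dim wild-type array 10 genes passed (6 of the 19), without it and the bright arrays 2 (Trem3 and Ly6c2, both of the 19), without PML/RARa replicate 4 alone 5, and without PML/RARa replicate 1 alone 69. Of the genes that did not pass without the dim array, Hp was then 2.12, Wfdc21 3.35, Cybb 1.51, Chil1 2.27 and Adgrg1 -1.56, and without it and the bright arrays 1.49, 2.95, 1.48, 2.05 and -1.31. Lcn2 (3.44), Clec5a (2.42) and Ly6c1 (1.87) did not pass without the dim array either. Their calls ended on leaving out 13, 17 and 14 of the 20 arrays, each alone. By limma with the GMP arrays alone, 0 genes passed, with 750 at an unadjusted p under 0.05 against 2360 with all arrays. The split also moved with the scaling: 192 higher and 117 lower with normexp and quantile normalization, 90 and 38 with the authors' value table, and 3708 and 6022 with normexp and the 75th percentile, where Lcn2 turned to -0.44.

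Of the gene lists, 11 of 27 differed in GMP by camera with its preset correlation and 0 with a correlation estimated from the data, whose adjusted p is given after each. Those higher in PML/RARa were secondary and tertiary granule (median 0.34, adjusted p = 0.0131, 0.456 estimated), primary granule (0.33, 0.0234, 0.456), monocyte and macrophage (0.20, 0.0158, 0.36), unfolded protein response (0.32, 0.022, 0.422), DNA repair by recombination (0.48, 0.0158, 0.456) and ribosome biogenesis and MYC targets (0.28, 0.0224, 0.456). Without the dim array the medians of these lists, in this order, were 0.35, 0.26, 0.27, 0.15, 0.10 and 0.08, and without the dim and the bright arrays 0.18, 0.33, 0.59, 0.43, -0.05 and 0.12. On slides 1, 2 and 3 the DNA repair median was -0.04, 0.68 and 0.01, that of ribosome biogenesis 0.18, 0.99 and 0.09, of primary granule genes 0.19, 0.80 and 0.19, of the unfolded protein response 0.34, 0.84 and 0.05 and of monocyte genes 0.55, 0.23 and 0.13. Slide 2, which holds the dim array, had the largest value of the first 4. Of the secondary and tertiary granule genes, 4 of 21 rose (Lcn2, Hp, Cybb and Chil1), 0 fell and 17 did not pass. Adjusted over the list alone, 7 rose and 1 fell. Its median was 0.22, -0.19 and 0.27 on slides 1, 2 and 3 and 0.24 with slide as a block. Of the primary granule genes 0 of 15 passed over all genes and 1 over the list alone, with Prtn3, the proteinase 3 gene, at 1.09 ± 0.24 (adjusted p = 0.0833). Of the monocyte genes 2 of 24 rose over all genes (Cybb and Ly6c1) and 6 over the list alone, where 1 fell.

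The remaining 5 of these lists were lower in PML/RARa GMP. Erythroid genes had a median of -0.85 with 19 of 21 negative (adjusted p = 0.00045, 0.221 estimated). Of these 0 passed over all genes, and 5 fell and 1 rose over the list alone. Within it the repressor gene Gfi1b was at -1.72 ± 0.37 (adjusted p = 0.0833) and the transferrin receptor gene Tfrc at 1.31 ± 0.27 (adjusted p = 0.0599). Megakaryocyte and platelet genes had a median of -0.70 (13 of 14 negative, adjusted p = 0.0149, 0.142 estimated), with Treml1 at -1.22 ± 0.38. Immediate early and heat shock genes had a median of -0.71 (17 of 19 negative, adjusted p = 0.00212, 0.321 estimated), with Jund at -1.35 ± 0.41 and the phosphatase gene Dusp1 at -1.28 ± 0.36. Stem and progenitor genes had a median of -0.49 (20 of 25 negative, adjusted p = 0.0208, 0.36 estimated). Adgrg1 fell over all genes and 3 members over the list alone. B cell genes had a median of -0.97 (adjusted p = 0.00622, 0.456 estimated), with Dntt at -1.59 ± 0.60. Without the dim array the erythroid, megakaryocyte, early response and stem cell medians were -0.73, -0.67, -0.91 and -0.51, and without it and the bright arrays -0.47, -0.46, -0.77 and -0.38. The B cell median was 0.22, -1.77 and -0.97 on slides 1, 2 and 3, -0.29 without the dim array and 0.24 without it and the bright arrays.

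In early promyelocytes, all 13 genes that passed were lower in PML/RARa, among them 3 secondary and tertiary granule genes and 4 mast cell and basophil genes. Ltf fell by 5.96 ± 0.73 (adjusted p = 0.00146), from 5.44 ± 1.46 (n = 3) to -0.52 ± 1.41 (n = 3). The neutrophil granule protein gene Ngp (-4.12 ± 0.59, adjusted p = 0.00482) and Retnlg (-5.82 ± 0.90, adjusted p = 0.0117) fell as well. So did the gelatinase gene Mmp9 (-4.98 ± 0.80, adjusted p = 0.0159) and the formyl peptide receptor gene Fpr2 (-4.60 ± 0.82, adjusted p = 0.0374). Of the mast cell and basophil genes, Cpa3 fell by 4.96 ± 0.53 (adjusted p = 0.000292), from 0.81 ± 0.69 to -4.15 ± 1.02. The mast cell protease gene Prss34 fell by 5.85 ± 0.75 (adjusted p = 0.00146). Ms4a2 was well above background on 3 of 3 wild-type and 0 of 3 PML/RARa arrays and was at least 9.07-fold lower (adjusted p = 0.000292). The lipoxygenase gene Alox5 (-3.05 ± 0.50, adjusted p = 0.021) and, of the stem and progenitor genes, Adgrg1 (-2.14 ± 0.37, adjusted p = 0.0279) fell too. In PML/RARa, Cpa3, Mmp9 and Fpr2 were above background on 1 of 3 arrays and Prss34, Retnlg and Alox5 on 2 of 3.

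By limma, 0 genes rose past the threshold in early promyelocytes, with 398 of either direction at an unadjusted p under 0.05. The higher values with the smallest p were the skin protein gene Dmkn at 1.25 ± 0.32 (adjusted p = 0.343), the clusterin gene Clu at 1.65 ± 0.42 (adjusted p = 0.36) and the stress gene Nupr1 at 1.99 ± 0.54 (adjusted p = 0.503). Rara was 0.48 ± 0.26 higher (adjusted p = 1), and Pml (-0.05 ± 0.27), S100a8 (-0.05 ± 0.71) and S100a9 (-0.63 ± 0.71) had an adjusted p of 1 as well. The genotypes did not overlap in any of the 13 genes. Ltf differed by -8.72 and -3.10 on slides 1 and 4, Cpa3 by -4.34 and -3.73, and Prss34 by -6.05 and -5.53. With slide as a block 10 genes passed, 8 of the 13 among them, and Ngp (adjusted p = 0.0549), Adgrg1 (0.113) and Fpr2 (0.27) did not. The count was 6 without wild-type early replicate 4 and 24 without wild-type early replicate 1, and by limma with the early arrays alone it was 0, with 524 at an unadjusted p under 0.05.

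By camera, 14 of 27 lists differed in early promyelocytes, 9 lower and 5 higher, and 1 passed with an estimated correlation, mast cell and basophil. Of its genes 4 of 15 fell over all genes and 7 over the list alone, with a median of -0.47, a mean of -1.69 and medians of -1.42 and -0.88 on slides 1 and 4 (adjusted p = 3.53e-17, 0.00569 estimated). Secondary and tertiary granule genes had a median of -0.79 (3 of 21 lower over all genes and 8 over the list alone, adjusted p = 3.82e-12, 0.0624 estimated, -1.72 and -0.46 on slides 1 and 4). The other lower lists were mature neutrophil (-0.69, 2 of 26 lower, adjusted p = 2.54e-05, 0.259 estimated), stem and progenitor (-0.29, 1 of 25, 1.3e-05, 0.0862), megakaryocyte and platelet (-0.67, 0 of 14, 0.00137, 0.0624), erythroid (-0.40, 0 of 21, 0.000495, 0.221), eosinophil (-1.97, 0 of 11, 7.67e-05, 0.221), myeloid transcription factors (-0.32, 0 of 28, 0.0126, 0.258) and genes high in human acute promyelocytic leukemia (-0.03, 1 of 21, 0.0353, 0.208). Erythroid and megakaryocyte members such as Klf1 (-1.67 ± 0.51), Gata1 (-1.98 ± 0.59) and Itgb3 (-1.04 ± 0.33) and the eosinophil genes Prg3 (-2.15 ± 0.65) and Epx (-1.42 ± 0.47) did not pass singly.

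The 5 higher lists had small shifts shared by many members. All 25 mitosis genes were positive (median 0.36, adjusted p = 2.33e-09, 0.141 estimated, 0.48 and 0.60 on slides 1 and 4), among them Plk1 at 1.09 ± 0.60 and Cenpf at 0.98 ± 0.45, and 0 passed singly. Primary granule genes were at 0.26 (adjusted p = 0.0353, 0.456 estimated), with the cathepsin gene Ctsc at 0.69 ± 0.37. Ribosome biogenesis and MYC targets were at 0.17 (0.0149, 0.456 estimated), cholesterol synthesis at 0.12 (0.0375, 0.221 estimated) and the unfolded protein response at 0.13 (0.0489, 0.456 estimated), with 0 members of each past the threshold.

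In late promyelocytes 14 genes passed, 7 higher and 7 lower in PML/RARa. Rara rose by 3.14 ± 0.24 (adjusted p = 3.6e-06), from -2.27 ± 0.29 (n = 3) to 0.87 ± 0.36 (n = 4), and by 3.05, 3.84 and 2.73 on slides 2, 4 and 5. The osteopontin gene Spp1, which encodes a secreted adhesion protein of macrophages, rose by 3.96 ± 0.41 (adjusted p = 0.000215), from -3.40 ± 0.05 to 0.55 ± 0.71. The lectin genes Clec2i (2.24 ± 0.30) and Clec2g (2.16 ± 0.38), the matrix gene Emilin2 (2.16 ± 0.31) and Clu (2.58 ± 0.39) rose as well. Irf8, the transcription factor that directs monocyte fate, fell by 2.29 ± 0.26 (adjusted p = 0.000612), from 2.63 ± 0.61 to 0.34 ± 0.27. The ganglioside synthase gene St3gal5 fell by 4.32 ± 0.58 (adjusted p = 0.00277). Ly86 (-2.25 ± 0.35, adjusted p = 0.0109), the tropomyosin gene Tpm4 (-1.60 ± 0.26, adjusted p = 0.0147) and Ngp (-3.03 ± 0.55, adjusted p = 0.04) fell as well. Rap1gap2, which encodes a regulator of a small GTPase, was above background on 3 of 3 wild-type and 0 of 4 PML/RARa arrays and was at least 5.77-fold lower (adjusted p = 0.0109). In PML/RARa, St3gal5 was above background on 3 of 4 arrays and Ly86 on 2 of 4.

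The genotypes did not overlap in any of these 14 genes. With slide as a block 18 genes passed, 12 of the 14 among them, and Ngp did not (adjusted p = 0.0807). Without the dim wild-type GMP array, which enters only through the shared estimate of the spread, 45 genes passed, all 14 among them. Without wild-type late replicate 4 the count was 5. Of the genes, 16 were higher and 31 lower in the authors' value table, and with normexp and quantile normalization 21 and 33. Pml (-0.43 ± 0.25), S100a8 (0.19 ± 0.79) and S100a9 (0.35 ± 0.79) had an adjusted p of 1. Over all genes, the genotypes did not overlap in 1219 genes in GMP, 1269 in early and 894 in late promyelocytes, which is 8.76%, 9.12% and 6.43% of the genes, where chance gives 5.71%, 10% and 5.71%.

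By camera 5 of 27 lists differed in late promyelocytes and 0 with an estimated correlation. Secondary and tertiary granule genes were lower (median -0.64, 17 of 21 negative, adjusted p = 2.88e-12, 0.0624 estimated), with 1 passing over all genes (Ngp) and 4 over the list alone, and with medians of -0.96, -0.64 and -0.87 on slides 2, 4 and 5. Monocyte and macrophage genes were lower (median -0.13, mean -0.38, adjusted p = 2.25e-05, 0.123 estimated), with Irf8 and Ly86 passing over all genes and 5 of 24 over the list alone. The medians on slides 2, 4 and 5 were -0.49, 0.11 and -0.23. Mitosis (0.29, 23 of 25 positive, adjusted p = 0.00171, 0.456 estimated), oxidative phosphorylation (0.18, 0.0235, 0.527) and ribosome biogenesis genes (0.21, 0.0312, 0.456, and 0.136 with slide as a block) were higher with 0 members past the threshold. The mitosis median was 0.80, -0.30 and -0.02 on slides 2, 4 and 5. Examples are Ccna2 at 0.51 ± 0.33, Bub1 at 0.45 ± 0.22, Cox6a1 at 0.58 ± 0.29, Atp5o at 0.41 ± 0.21, Nop58 at 0.52 ± 0.28 and Nolc1 at 0.32 ± 0.22.

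**Figure D2:**
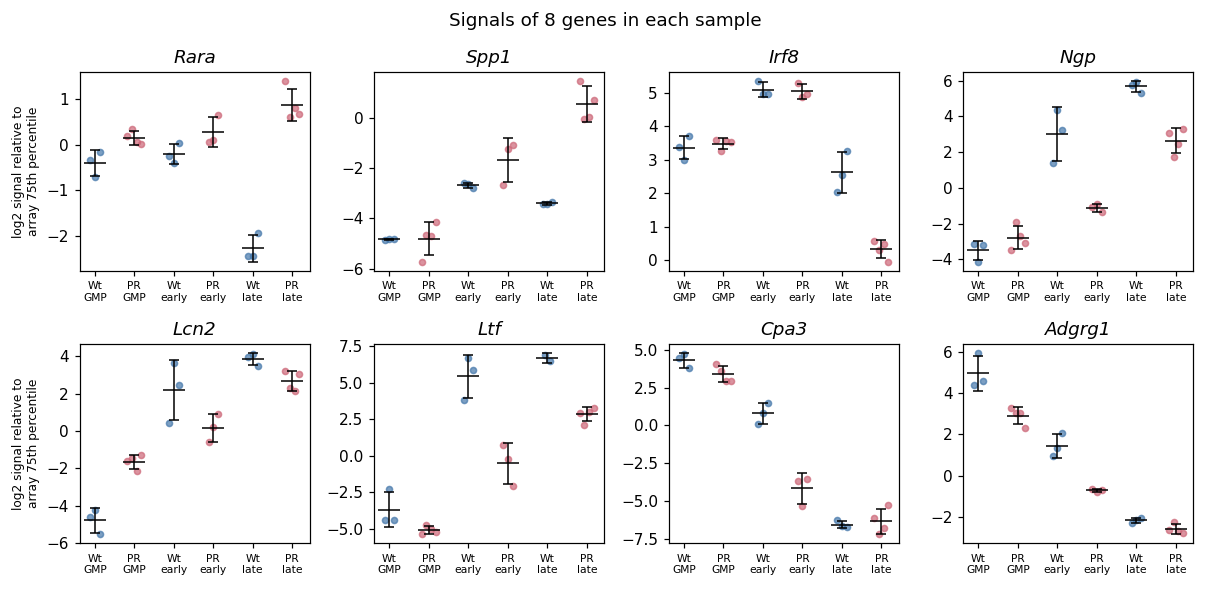
Signals of 8 genes in each sample (log2, relative to the 75th percentile of each array) for wild type (Wt) and PML/RARa (PR) in GMP, early and late promyelocytes, with mean ± SD. In late promyelocytes Rara lies at 0.87 in PML/RARa and -2.27 in wild type and Irf8 at 0.34 and 2.63, and in early promyelocytes Ltf lies at -0.52 and 5.44.

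Averaged over the 3 populations, 43 genes differed by genotype, 15 higher and 28 lower, of which 30 also passed with slide as a block. With normexp and the 75th percentile 27 were higher and 11 lower, and 52 and 60 were in the authors' value table. The largest rises were Clu (1.85 ± 0.23, adjusted p = 0.000953), Clec5a (1.83 ± 0.28, adjusted p = 0.00544), the GTPase gene Rhoj (1.83 ± 0.32, adjusted p = 0.0174, and 0.0637 with slide as a block) and Spp1 (1.66 ± 0.24, adjusted p = 0.00398), and Rara rose by 1.39 ± 0.14 (adjusted p = 0.000281). Spp1 and Rhoj, and Ltf and Retnlg below, were above background on 0 of 3 wild-type GMP arrays, and Rhoj on 0 of 3 wild-type early arrays as well. Clu was above it on 1 of 3 wild-type GMP and 1 of 3 wild-type early arrays. Mmp9 below was above it on 1 of 3 wild-type GMP and 1 of 3 PML/RARa early arrays. The averages of these genes therefore include signal read at background and are not exact sizes. The largest falls were Ltf (-3.73 ± 0.42, adjusted p = 0.000418), Retnlg (-3.53 ± 0.50, adjusted p = 0.00283), St3gal5 (-3.02 ± 0.34, adjusted p = 0.000418) and Mmp9 (-2.88 ± 0.44, adjusted p = 0.00544). Megakaryocyte and platelet genes were the list of 12 passing by camera that also passed with an estimated correlation, with all 14 genes negative, a median of -0.52 and adjusted p = 0.000157 (0.0361 estimated). The median was -0.43 without the dim array and -0.38 without it and the bright arrays. Of the 14 genes, 9 were above background on all wild-type GMP arrays and 7 on all PML/RARa early arrays, so these values are read at background in part.

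The genotype effect was tested for a difference between populations. From GMP to early promyelocytes 1 gene passed, Prss34, whose effect changed by -7.44 ± 1.03 (adjusted p = 0.0193, 0.0597 with slide as a block), and by -6.84 without the dim array, where by limma 0 genes passed (402 at an unadjusted p under 0.05). From GMP to late promyelocytes 8 passed, 2 higher and 6 lower, with a median over all genes of 0.16 (3776 and 1453 with normexp and the 75th percentile). Without the dim array 13 passed, all 8 among them, and without it and the bright arrays 0 (limma, 668 at an unadjusted p under 0.05), where Rara was at 2.64 and Prkcb at -2.60. With PML/RARa late replicate 1 counted as early 0 passed (961), and without 1 array 4 to 13. The effect on Rara was larger in late promyelocytes by 2.59 ± 0.34 (adjusted p = 0.00452) and that on Spp1 by 3.94 ± 0.58 (adjusted p = 0.0127), while the effects on Irf8 (-2.41 ± 0.37, adjusted p = 0.018), the kinase gene Prkcb (-2.64 ± 0.33, adjusted p = 0.00452), Alcam (-2.42 ± 0.39, adjusted p = 0.0216) and Ifi202b (-2.92 ± 0.47, adjusted p = 0.0216) were lower. From early to late promyelocytes the genes that passed this test were Rara (2.66 ± 0.35, adjusted p = 0.00501), Ms4a2 (4.76 ± 0.57, adjusted p = 0.00282) and Cpa3 (5.17 ± 0.73, adjusted p = 0.00813). Part of these values is read at background: Cpa3 was above it on 0 of 3 wild-type and 0 of 4 PML/RARa late arrays, so no late effect on it was measured, Ms4a2 on 0 of 3 PML/RARa early arrays and Spp1 on 0 of 3 wild-type GMP arrays. With slide as a block Ms4a2 passed, and Rara and Cpa3 had an adjusted p of 0.0711.

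The granule lists followed the same test. The effect on secondary and tertiary granule genes was lower in early promyelocytes than in GMP (median -1.42, camera adjusted p = 7.11e-14, 0.0511 estimated) and lower in late promyelocytes than in GMP (median -1.23, adjusted p = 4.16e-10, 0.0741 estimated), though no more than 11 of the 21 were above background on all wild-type GMP arrays. The effect on mast cell and basophil genes differed between early and late promyelocytes by a median of 0.85 (adjusted p = 3.81e-11, 0.045 estimated). Of these 15 genes 6 were above background on all wild-type late arrays, so for the others a late effect is read at background in part. The effect on monocyte genes differed between GMP and late promyelocytes by -0.58 (adjusted p = 3.27e-06, 0.08 estimated). Across all genes the genotype effect was also set against wild-type maturation measured in other arrays: r was -0.0768 in GMP (exact permutation p = 0.83), 0.278 in early promyelocytes (exact permutation p = 0.1, the smallest that 20 assignments can give) and -0.0326 in late promyelocytes (exact permutation p = 0.83).

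**Figure D3:**
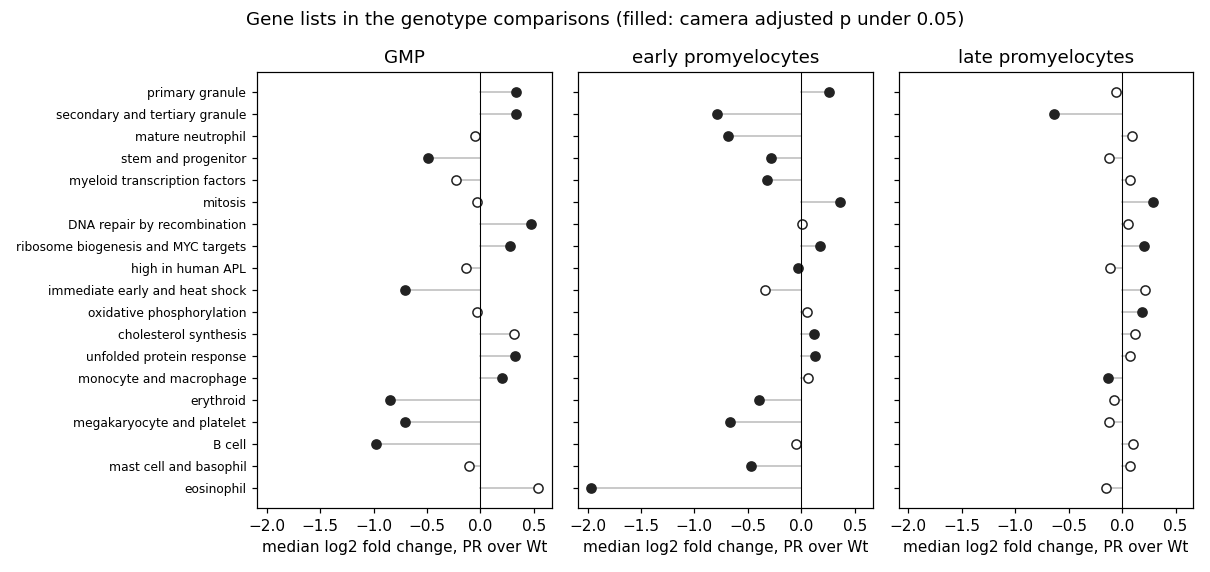
Median log2 fold change of 19 gene lists, PML/RARa over wild type, in GMP, early and late promyelocytes, with filled points where the camera adjusted p is under 0.05. Secondary and tertiary granule genes lie at 0.34, -0.79 and -0.64 in the 3 populations, and mast cell and basophil genes at -0.47 in early promyelocytes.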

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

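The tests of array brightness, of mast cells or basophils and of the stage of PML/RARa late replicate 1 were chosen after the results were seen; the other tests in this part were set beforehand.

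The test for a difference of the genotype effect between populations passed for 11 genes, counting Cpa3, for which no late effect was measured. From GMP to early promyelocytes this was Prss34 (-7.44). From GMP to late promyelocytes it was Irf8 (-2.41), Cybb (-2.20), Trem3 (-2.38), Ifi202b (-2.92), Prkcb (-2.64), Alcam (-2.42), Rara (2.59) and Spp1 (3.94). From early to late promyelocytes it was Rara (2.66), Cpa3 (5.17) and Ms4a2 (4.76). Trem3 and Cybb were higher in PML/RARa GMP (2.42 and 1.56) and differed little in late promyelocytes (0.04 and -0.64). Prkcb was 1.65 in GMP and -0.98 in late promyelocytes (adjusted p = 0.00697 and 0.176). Irf8 was 0.12 in GMP, -0.05 in early and -2.29 in late promyelocytes. Prss34 was 1.59 in GMP and -5.85 in early promyelocytes. Cpa3 was -4.96 in early promyelocytes and above background on no late array (0), so no change of its effect was measured. Ms4a2, above background on 0 of 3 PML/RARa early arrays, was at least 9.07-fold lower there. Its difference between early and late promyelocytes is therefore not an exact value.

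In single samples, 5 of the named genes had a value far from the other 3 of its group, where the gap divided by the whole range passed Dixon's critical value for 4 samples: Treml1 in PML/RARa GMP replicate 2 (-0.24 against -1.23 to -1.07; 0.839), Gimap1 in PML/RARa GMP replicate 4 (1.01 against 1.68 to 1.76; 0.884), and Gusb (3.68 against 3.25 to 3.32; 0.844), Itgb3 (1.09 against 0.24 to 0.33; 0.892) and Cenpf (1.31 against 2.86 to 3.06; 0.887) in PML/RARa late replicate 1. Of 190 groups of 4 values tested, chance gives about 1 in 20 if the groups are independent, and these 5 are fewer. Gusb, Itgb3 and Cenpf share 1 sample, the one whose labels differ. Among probes without a gene symbol, 5 passed in GMP, all higher in PML/RARa, 1 in early promyelocytes and 2 in late promyelocytes, all lower.

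The first pattern weighed is the higher list median of secondary and tertiary granule genes in PML/RARa GMP (0.34 ± 0.37). In these patterns the value is the median of the genes' fold changes. The SE beside it is that of the genotype difference in the samples' median signals over the list, a related but other measure. The median is smaller than this SE, so the rise itself is not set apart from 0. The verdicts on slide use this SE too. No test excluded an explanation. Array brightness stays open: without the dim and the bright arrays the median was 0.18 ± 0.51. Slide stays open too, with a median of 0.24 ± 0.39 with slide as a block. More mature cells among the sorted PML/RARa GMP were looked for through the genes that rise from early to late promyelocytes. The explanation was set to predict a correlation above 0. Across genes outside the list that correlation was -0.0811 (exact permutation p = 0.83). This does not decide, since that step, which shares no array with the GMP, is not the one that follows GMP. Over all genes the correlation ran from -0.184 to 0.163 as single arrays were left out.

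The second pattern is the fall of mast cell and basophil genes in PML/RARa early promyelocytes (median -0.47 ± 0.37). The tables argue against slide, since with slide as a block the median was -0.82 ± 0.32. Mast cells or basophils among the sorted wild-type early promyelocytes are a candidate explanation, although the cells were enriched for c-kit and double sorted, and mast cells carry c-kit as well. Of the 9 members above background on all wild-type early arrays, 7 were lower by at least 1, a share of 0.778; the exceptions were Hdc (4.56 in wild type, -0.46 ± 0.31) and Slc18a2 (-0.75, -0.19 ± 0.29), while the other bright members were Mcpt8 (2.76, -1.23 ± 0.34), Prss34 (1.41) and Cpa3 (0.81). Of the 15 members, 12 were above background in wild-type GMP and 2 are also in another list. The same values could therefore come from the promyelocytes themselves, a difference of genotype that was not tested. A difference in maturity of the sorted cells was not weighed for this pattern. Over all genes the genotype effect here correlated with wild-type maturation at 0.278 (exact permutation p = 0.1, the smallest of 20 assignments). Secondary and tertiary granule genes, which rise with maturation, were lower in the same cells.

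The third pattern is the fall of secondary and tertiary granule genes in PML/RARa late promyelocytes (median -0.64 ± 0.37). The tables argue against slide (-0.79 ± 0.39 with slide as a block). They argue against a wrong label of PML/RARa late replicate 1 as well. Without that sample the median was -0.65 ± 0.40, which did not decide by the bound set, but over 597 genes outside the list it lay at 1.02 ± 0.05 on the axis from the early (0) to the late samples (1), where early promyelocytes would lie near 0. Fewer mature cells among the sorted PML/RARa late promyelocytes stay open: across genes outside the list the correlation with the step from GMP to early promyelocytes was -0.0093 (exact permutation p = 1). A direct effect of PML/RARa on these genes is another possible explanation. The design compares the genotypes, and such an effect was not tested apart from the explanations above.

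Other splits of the same samples were counted for each comparison. For GMP, 4 of 35 splits gave at least the real 19 genes, so chance cannot be excluded; the highest other count was 166, from the split that parts wild-type replicate 3 and PML/RARa replicates 3 and 4 from the rest. For the GMP lists, 4 of 35 splits gave at least the real 11 (highest other 13), so chance cannot be excluded. For late promyelocytes only the real split of 35 gave as many as the 14 genes (highest other 1), the smallest share possible. For the 5 lists 16 of 35 splits gave as many (highest other 12), so chance cannot be excluded. For early promyelocytes 10 splits are too few for a share under 0.05: the real split gave 13 genes and 14 lists and the highest others 1 and 11. The same holds for the wild-type steps, 779 genes against 95 and 674 against 1 in the highest other split of 10, each real split being the only 1 as large. In PML/RARa only the real split was as large for either step (1 of 35 each, 823 against 164 and 803 against 50). Of 100 splits within populations, only the real one was as large for the averaged effect (43 genes against 3). The same held for the difference between late promyelocytes and GMP (8 against 4). Without the dim and the bright GMP arrays that count was 0 (limma, 668 at an unadjusted p under 0.05). Chance cannot be excluded for early promyelocytes against GMP (10 splits as large, 1 gene against 342). Nor can it for late against early promyelocytes (5 splits, 3 genes against 3). These shares were not adjusted for the number of comparisons, so a share of 1 in 35 or 1 in 100 does not by itself exclude chance.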

How the results depend on the processing

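Leaving out the dim GMP array, leaving out the dim and the bright GMP arrays, keeping outlier spots and testing accessions without a symbol were chosen after the results were seen; the other alternatives were set beforehand.

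Of 7138 values of named genes under the alternatives, 6641 kept direction and side of the threshold, 355 lost and 73 gained a call, and 69 changed direction. These include values that did not pass in the report and so had no call to lose. Of 652 counts and correlations 469 stayed, 165 moved and 18 changed direction. A count was said to stay by its size alone, within a set ratio of that in the report, whichever genes it held. For example, the 779 genes of the wild-type GMP-to-early step became 680 without the dim array, with 529 shared. Rara (1.93 to 3.31, adjusted p from 7.12e-08 to 0.0181) and St3gal5 (-4.79 to -2.17, adjusted p from 0.000344 to 0.0396) in late promyelocytes kept direction and call in all 38 alternatives. The named genes that passed in GMP lost their call in 1 (Trem3) to 26 (Clec5a) of the 38. Leaving out the dim array is counted both by itself and among the single arrays left out. Leaving out an array of a group that is not compared changes the spread only. For the values that follow the cause was not tested, except that the compared groups alone leave fewer samples for the spread, and that the normexp offset of 50 exceeds the 75th percentile of the dim array (36.2), which shrinks its differences. Between 51.5 and 85.6% of the probes of an array were well above background, so a gene dim in all groups is not read and a change against a group at background has no exact size. A block for the scan day was not run, as all arrays share it. Genes counted as shared are those that also passed in the report.

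With quantile normalization the counts of genes were 33 in GMP (18 shared), 3 for the early against GMP effect (1 shared) and 6 for the late against early effect (3 shared). Lists numbered 8 in early promyelocytes and 3 in late promyelocytes, with a maturation correlation of 0.0223 in late promyelocytes.

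With normexp and the 75th percentile the counts of genes were 9730 in GMP (12 shared), 2 in early promyelocytes (2 shared), 2 for the early against GMP effect (1 shared), 5229 for the late against GMP effect (7 shared), 0 for the late against early effect (limma, 100 at an unadjusted p under 0.05), 3176 for the wild-type GMP-to-early step (529 shared), 381 for the wild-type early-to-late step (314 shared), 482 for the PML/RARa GMP-to-early step (391 shared) and 479 for the PML/RARa early-to-late step (402 shared). Lists numbered 8 in late promyelocytes, with a maturation correlation of 0.144 in late promyelocytes. Lcn2 turned to -0.44 in GMP. S100a8 turned to -0.35 in GMP, 0.0969 in early promyelocytes, -0.0161 averaged, 0.45 for the early against GMP effect and 0.56 for the late against GMP effect. Pml turned to 0.37 in GMP, 0.0733 in early promyelocytes, 0.01 averaged, -0.30 for the early against GMP effect, -0.79 for the late against GMP effect and 0.11 for the wild-type GMP-to-early step. S100a9 turned to -0.97 in GMP, -0.48 averaged, 0.42 for the early against GMP effect and 1.06 for the late against GMP effect. Rhoj turned to -0.16 averaged. Rara turned to 0.0323 for the early against GMP effect. Mpo turned to 0.35 for the wild-type GMP-to-early step. Ctsg turned to 0.0234 for the wild-type early-to-late step.

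With normexp and quantile normalization the counts of genes were 309 in GMP (18 shared), 54 in late promyelocytes (9 shared), 135 averaged (37 shared), 2 for the early against GMP effect (1 shared), 63 for the late against GMP effect (8 shared) and 1348 for the wild-type GMP-to-early step (709 shared). Lists numbered 3 in late promyelocytes, with a maturation correlation of 0.0189 in late promyelocytes. Pml turned to 0.0163 in early promyelocytes. S100a8 turned to 0.0118 in early promyelocytes.

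From the authors' value table the counts of genes were 128 in GMP (18 shared), 20 in early promyelocytes (12 shared), 47 in late promyelocytes (11 shared), 112 averaged (41 shared), 6 for the early against GMP effect (1 shared), 60 for the late against GMP effect (7 shared), 10 for the late against early effect (3 shared) and 1282 for the wild-type GMP-to-early step (730 shared), with a maturation correlation of 0.0389 in late promyelocytes. Pml turned to 0.013 in early promyelocytes. S100a8 turned to 0.0185 in early promyelocytes. Mpo turned to 0.0269 for the wild-type GMP-to-early step, -0.0374 for the PML/RARa GMP-to-early step and 0.0013 for the PML/RARa early-to-late step. Ctsg turned to 0.13 for the wild-type early-to-late step.

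With no filter on dim probes the count of genes was 11 in GMP (10 shared), with a maturation correlation of 0.0568 in GMP.

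With probes above background on at least 10 arrays the counts of genes were 33 in GMP (19 shared), 2 for the early against GMP effect (1 shared) and 8 for the late against early effect (3 shared).

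With the mean over a gene's probes the counts of genes were 34 in GMP (16 shared) and 26 in late promyelocytes (14 shared). Pml turned to -0.0493 for the late against GMP effect. Mki67 turned to 0.0983 for the PML/RARa early-to-late step.

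With trend and robust variances the counts of genes were 41 in GMP (19 shared), 3 for the early against GMP effect (1 shared), 13 for the late against GMP effect (8 shared) and 6 for the late against early effect (3 shared).

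With array weights the counts of genes were 55 in GMP (18 shared), 22 in early promyelocytes (12 shared), 161 in late promyelocytes (14 shared), 189 averaged (43 shared), 64 for the late against GMP effect (8 shared), 16 for the late against early effect (3 shared), 1396 for the wild-type GMP-to-early step (765 shared), 1816 for the wild-type early-to-late step (674 shared), 2043 for the PML/RARa GMP-to-early step (811 shared) and 2233 for the PML/RARa early-to-late step (801 shared). Rara turned to 0.018 for the early against GMP effect. Pml turned to -0.0724 for the late against GMP effect.

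With the compared groups alone the counts of genes were 0 in GMP (limma, 750 at an unadjusted p under 0.05), 0 in early promyelocytes (limma, 524 at an unadjusted p under 0.05), 0 for the late against early effect (limma, 553 at an unadjusted p under 0.05) and 91 for the wild-type GMP-to-early step (91 shared).

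With replicate as a block the counts of genes were 11 in GMP (10 shared) and 7 in early promyelocytes (6 shared). They were 0 for the early against GMP effect (limma, 601 at an unadjusted p under 0.05). For the late against GMP effect 2 passed (2 shared) and for the late against early effect 1 (1 shared). The labels do not say what the replicate numbers mark. S100a8 turned to -0.58 in late promyelocytes and -0.35 for the late against early effect. S100a9 turned to -0.31 in late promyelocytes. Residuals of samples with the same number had a mean correlation of -0.0174 over 40 pairs, and 2 of the 20 samples correlated best with their own number.

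With replicate within genotype as a random block the counts of genes were 22 averaged (22 shared), 3 for the early against GMP effect (1 shared), 20 for the late against GMP effect (8 shared) and 8 for the late against early effect (3 shared).

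With slide as a block the counts of genes were 0 for the early against GMP effect (limma, 886 at an unadjusted p under 0.05) and 1 for the late against early effect (1 shared). Ctsg turned to 0.0442 for the wild-type early-to-late step.

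With PML/RARa late replicate 1 counted as early the counts of genes were 2 in GMP (2 shared), 3 in late promyelocytes (3 shared), 21 averaged (21 shared), 0 for the late against GMP effect (limma, 961 at an unadjusted p under 0.05), 225 for the wild-type early-to-late step (224 shared) and 0 for the PML/RARa early-to-late step (limma, 1507 at an unadjusted p under 0.05). Lists numbered 3 in late promyelocytes. Pml turned to 0.049 in early promyelocytes. Rara turned to 0.21 for the early against GMP effect. Mki67 turned to 0.34 for the PML/RARa early-to-late step.

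At an adjusted p under 0.1 the counts of genes were 79 in GMP (19 shared), 31 in late promyelocytes (14 shared), 5 for the early against GMP effect (1 shared), 25 for the late against GMP effect (8 shared) and 8 for the late against early effect (3 shared).

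With camera at an estimated correlation 0, 1 and 0 lists passed in GMP, early and late promyelocytes (limma, 2, 11 and 2 at an unadjusted p under 0.05), and by fry 2, 2 and 0 (8, 11 and 2).

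With the genes past the threshold in the maturation step the maturation correlation was 0.246 in GMP.

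By Spearman the maturation correlation was 0.0782 in late promyelocytes.

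Without the dim GMP array (wild-type replicate 3) the counts of genes were 10 in GMP (6 shared), 45 in late promyelocytes (14 shared), 0 for the early against GMP effect (limma, 402 at an unadjusted p under 0.05), 13 for the late against GMP effect (8 shared), 8 for the late against early effect (3 shared), 1035 for the wild-type early-to-late step (674 shared), 1237 for the PML/RARa GMP-to-early step (823 shared) and 1221 for the PML/RARa early-to-late step (803 shared). Lists numbered 7 in GMP, with a maturation correlation of 0.163 in GMP and 0.026 in late promyelocytes. Rara turned to 0.0855 for the early against GMP effect. Pml turned to -0.16 for the late against GMP effect.

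Without it and the bright arrays (PML/RARa replicates 3 and 4) the counts of genes were 2 in GMP (2 shared), 40 in late promyelocytes (14 shared), 28 averaged (22 shared), 0 for the early against GMP effect (limma, 455 at an unadjusted p under 0.05), 0 for the late against GMP effect (limma, 668 at an unadjusted p under 0.05), 1133 for the wild-type early-to-late step (672 shared) and 1368 for the PML/RARa early-to-late step (800 shared), with a maturation correlation of 0.24 in GMP and 0.026 in late promyelocytes. Pml turned to -0.0314 for the early against GMP effect and -0.41 for the late against GMP effect.

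With outlier spots kept Ctsg turned to 0.0662 for the wild-type early-to-late step.

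Leaving out each array in turn gave these ranges. Genes that passed numbered 5 (without PML/RARa GMP replicate 4) to 69 (without PML/RARa GMP replicate 1) in GMP, 6 (without wild-type early replicate 4) to 24 (without wild-type early replicate 1) in early promyelocytes and 5 (without wild-type late replicate 4) to 45 (without wild-type GMP replicate 3) in late promyelocytes. Averaged over the populations they numbered 21 (without wild-type early replicate 4) to 51 (without wild-type GMP replicate 3). Effects that differed between populations ran from 0 (without wild-type GMP replicate 3, limma, 402 at an unadjusted p under 0.05) to 5 (without PML/RARa late replicate 4) for the early against GMP effect, from 4 (without PML/RARa GMP replicate 4) to 13 (without wild-type GMP replicate 3) for the late against GMP effect and from 3 (without wild-type GMP replicate 2) to 8 (without wild-type GMP replicate 3) for the late against early effect. Steps within wild type had 488 (without wild-type early replicate 1) to 945 (without wild-type GMP replicate 2) genes from GMP to early and 394 (without wild-type late replicate 2) to 1035 (without wild-type GMP replicate 3) genes from early to late, and those within PML/RARa 473 (without PML/RARa early replicate 3) to 1237 (without wild-type GMP replicate 3) from GMP to early and 508 (without PML/RARa early replicate 1) to 1221 (without wild-type GMP replicate 3) from early to late. Lists numbered 5 (without wild-type GMP replicate 4) to 13 (without PML/RARa GMP replicate 4) in GMP, 8 (without wild-type early replicate 3) to 17 (without wild-type early replicate 4) in early promyelocytes and 2 (without wild-type late replicate 1) to 5 (without wild-type GMP replicate 2) in late promyelocytes. Maturation correlations ran from -0.184 (without wild-type early replicate 3) to 0.163 (without wild-type GMP replicate 3) in GMP, 0.19 to 0.333 in early promyelocytes and -0.148 (without wild-type early replicate 3) to 0.0675 (without PML/RARa late replicate 2) in late promyelocytes.

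Named genes that changed direction without 1 array were these, with the range over all such omissions; none had an adjusted p under 0.05 where it turned. Pml in early promyelocytes (-0.0903 to 0.0138, turned without PML/RARa early replicate 3) and S100a8 in early promyelocytes (-0.92 to 0.65, turned without wild-type early replicate 3, wild-type early replicate 4 and PML/RARa early replicate 1). S100a9 in early promyelocytes (-1.53 to 0.15, turned without wild-type early replicate 3 and PML/RARa early replicate 1) and S100a8 in late promyelocytes (-0.16 to 0.55, turned without wild-type late replicate 4). S100a9 averaged (-0.0279 to 0.53, turned without wild-type early replicate 1) and Rara for the early against GMP effect (-0.26 to 0.0855, turned without wild-type GMP replicate 3, wild-type early replicate 4, PML/RARa early replicate 1 and PML/RARa early replicate 2). Pml for the late against GMP effect (-0.16 to 0.42, turned without wild-type GMP replicate 3) and S100a8 for the late against early effect (-0.46 to 1.11, turned without wild-type early replicate 3, wild-type late replicate 4 and PML/RARa early replicate 1). Ctsg for the wild-type early-to-late step (-0.20 to 0.12, turned without wild-type early replicate 1 and wild-type late replicate 4) and Rara for the PML/RARa GMP-to-early step (-0.0632 to 0.23, turned without PML/RARa early replicate 3). Mpo for the PML/RARa early-to-late step (-0.43 to 0.056, turned without PML/RARa early replicate 3) and Ctsg for the PML/RARa early-to-late step (-0.16 to 0.24, turned without PML/RARa late replicate 3). Mki67 for the PML/RARa early-to-late step (-0.16 to 0.19, turned without PML/RARa early replicate 2, PML/RARa early replicate 3, PML/RARa late replicate 1 and PML/RARa late replicate 3).

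Calls of named genes that ended without 1 of the 20 arrays are given with the number of such arrays and, in parentheses, the highest adjusted p and the array left out there. In GMP these were Lcn2 13 (up to 0.13, PML/RARa GMP replicate 4), Clec5a 17 (up to 0.162, wild-type GMP replicate 3), Chil1 4 (up to 0.1, wild-type GMP replicate 3), Hp 4 (up to 0.0828, wild-type GMP replicate 4), Adgrg1 3 (up to 0.0902, PML/RARa GMP replicate 4), Cybb 4 (up to 0.0902, PML/RARa GMP replicate 4), Wfdc21 5 (up to 0.0902, PML/RARa GMP replicate 4) and Ly6c1 14 (up to 0.164, wild-type GMP replicate 3). In late promyelocytes these were Ngp 15 (up to 0.25, wild-type late replicate 2), Rap1gap2 3 (up to 0.092, wild-type late replicate 2), Tpm4 4 (up to 0.145, wild-type late replicate 4), Clec2g 8 (up to 0.189, wild-type late replicate 1), Emilin2 1 (up to 0.0536, wild-type late replicate 4), Clu 1 (up to 0.114, wild-type late replicate 4) and Ly86 1 (up to 0.0646, wild-type late replicate 4). For the late against GMP effect these were Alcam 6 (up to 0.101, wild-type late replicate 1), Ifi202b 6 (up to 0.101, wild-type late replicate 1) and Irf8 3 (up to 0.0556, PML/RARa late replicate 4). For the wild-type GMP-to-early step these were Elane 4 (up to 0.215, wild-type early replicate 4). For the early against GMP effect these were Prss34 8 (up to 0.109, PML/RARa early replicate 1). In early promyelocytes these were Fpr2 12 (up to 0.287, PML/RARa early replicate 3), Retnlg 4 (up to 0.12, PML/RARa early replicate 3), Mmp9 3 (up to 0.153, PML/RARa early replicate 3), Alox5 4 (up to 0.181, wild-type early replicate 4) and Adgrg1 7 (up to 0.261, wild-type early replicate 4). For the wild-type early-to-late step these were Ngp 2 (up to 0.0556, wild-type early replicate 1) and S100a8 3 (up to 0.155, wild-type late replicate 1). Averaged these were Rhoj 2 (up to 0.0569, wild-type early replicate 4).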

Other observations

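The test of the Rara probe was chosen after the result was seen.

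8 gene lists passed in no genotype comparison without a block. Their GMP medians are given here over all GMP arrays only. Averaged over populations, the retinoic acid median was -0.26 with all arrays, -0.0086 without the dim array and 0.023 without it and the bright arrays. The T and NK cell median was -0.30, -0.13 and -0.06 in the same settings. With slide as a block T and NK cell genes passed in the average (camera adjusted p = 0.0349, against 0.0584 without it). Retinoic acid response genes had medians of -0.38, -0.30 and -0.13 in GMP, early and late promyelocytes (camera adjusted p = 0.402, 0.269 and 0.837), of 14 genes tested, with Rara the 1 that passed. In early promyelocytes their member Rarg was at -0.94 ± 0.46. Interferon response genes had medians of -0.33, -0.08 and -0.05 (adjusted p = 0.102, 0.854 and 0.359), inflammatory mediators of NF-kB -0.32, -0.07 and 0.09 (0.253, 0.789 and 0.146), p53 targets -0.16, -0.10 and 0.09 (0.837, 0.0665 and 0.837) and DNA replication genes 0.15, -0.03 and 0.17 (0.139, 0.837 and 0.178). For glycolysis and hypoxia they were -0.16, 0.04 and 0.21 (0.555, 0.537 and 0.22), for dendritic cell and MHC class II genes -0.30, -0.20 and 0.16 (0.837, 0.197 and 0.955) and for T and NK cell genes -0.64, -0.38 and 0.11 (0.115, 0.112 and 0.955). Other values of early promyelocytes are Thbs1 at -2.15 ± 0.83 and Lyz2, the lysozyme gene, at -0.72 ± 0.29, and of GMP Gusb at 0.67 ± 0.24. Of the sex-linked genes, Xist lay between -1.83 and 0.06 and was above background on all 20 arrays, and Ddx3y lay between -4.48 and -0.09 and was above background on 19, as in mixes of both sexes.

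Rara was 3.14 ± 0.24 higher in PML/RARa late promyelocytes. A candidate explanation is that its probe reads the transgene transcript, which carries part of Rara and whose promoter comes from the human counterpart of S100a8. If that transcript followed the mouse S100a8 gene, the excess of the Rara signal over wild type should rise from GMP to early promyelocytes by at least the fold of S100a8 in the same samples, 52.5. The excess, in units of the 75th percentile, was 0.346 ± 0.102 in GMP, 0.355 ± 0.186 in early and 1.67 ± 0.258 in late promyelocytes, so the ratio of early to GMP was 1.03 ± 0.619. This argues against a transcript that follows S100a8 only if the GMP excess is transgene signal. The Rara effect did not pass in GMP (limma adjusted p = 0.267) or early promyelocytes, and the GMP excess includes the dim and the bright arrays. The ratio therefore does not decide. The step from early to late promyelocytes, where the excess rose most, was not used. A transgene with its own course, or a change of Rara itself, stays open as well. The part of the gene that the probe reads was not compared with the transgene. In wild type Rara fell by 2.06 from early to late promyelocytes, which PML/RARa cells did not show (0.60 ± 0.24, adjusted p = 0.199).

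The array carries 14 custom probes whose targets are not given in the sources used here. None passed in a genotype comparison (limma, 0 probes, with 3, 2 and 2 at an unadjusted p under 0.05 in GMP, early and late promyelocytes), and the smallest adjusted p was 0.207, for a probe at 0.74 in GMP.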
